A study of Mus musculus with 24 samples.

How the data were processed

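RNA from heart, liver, skeletal muscle and the subcutaneous 4T1 tumour of Balb/c mice was measured on Illumina MouseRef-8 v2 BeadChips, a 1-colour array on which each probe sits on many beads. Per the labels, the mice had either fasted for 48 h or fed freely, and 3 mice per diet gave 24 arrays in 8 groups of 3. The 2 leading letters of each title recur in all 4 tissues and were read as the mouse.

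The authors deposited average bead signal intensity per probe together with a detection p-value, exported from GenomeStudio 1.1.1 without normalization or background subtraction, per the file headers. The detection p-value compares a probe with the negative control beads of the same array, per the file headers. A second deposited table holds a score per probe and array; set against the intensities, each column matched the z-score of log10 signal over all probes of that array, so its scale and centring are known from the values. The authors' own description of that step is not given in the sources used here. The highest gap between that z-score and the deposited score was 4.76e-08, and the columns' medians lay between -0.491 and -0.166. That table served as an alternative. No per-sample column was left unused. No chip number or scan day was read from the tables, so chips were not tested as batches. The running numbers in the titles were lower for every fasted sample than for any fed one. Whether they give the order of processing is not stated, but a batch that followed them could not be told apart from diet.

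The intensities were background-corrected from the detection p-values, given an offset of 16, quantile-normalized over the 24 arrays and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. The array holds 25697 probes. Of these, 23681 were named through their Entrez number and 1202 through their accession in a RefSeq gene table of assembly GRCm38.p6, used for names alone, and 814 kept the symbol of the array's own annotation. This changed 4601 symbols. The probe with the highest mean stood for each of 17944 genes. A gene was tested in a tissue if its probe had a detection p below 0.01 on at least 3 of the 6 arrays. Fasted and fed arrays were compared within each tissue with lmFit and eBayes, and genes were called at a Benjamini-Hochberg adjusted p below 0.05. All fold changes are fasted over fed. Differences between the fasting effect in the tumour and that in a normal tissue, or in the mean of the 3 normal tissues, came from 1 fit of the 8 groups with a pooled spread. Where a probe was detected on none of a group's 3 arrays, the ratio is given as at least N-fold. A difference between tissues that involves such a group is given as a bound where placing the group at its floor makes the difference smaller, and without a size otherwise. It sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the probe's own value and the lowest value among detected probes.

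Before the data were examined, 45 gene lists were fixed, 16 of cell type markers and 29 of pathways and complexes. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, again with the correlation estimated per list, and with fry, which asks whether the members move on balance in 1 direction. By fry 11 of 38 lists passed in heart, 3 of 34 in liver, 17 of 35 in muscle and 0 of 32 in the tumour, against 5, 8, 11 and 10 by camera. None of the camera calls held with the estimated correlation in any tissue. Adjusted p-values of lists cover the lists tested in that tissue. The genes to be named were fixed at the same time. Per tissue these were the 8 called genes with the highest and the 8 with the lowest fold change among those whose fasted and fed values did not overlap, leaving out clone and accession names. If none was called, the genes with the 5 lowest p-values in each direction were taken. Also named were up to 4 called members of a described list, a set of known fasting, growth and tumour genes whatever their result, genes called in the same direction in all 4 tissues, and 8 genes in each direction for the tumour against the mean of the normal tissues. The lists of known genes named Ucp3 and Cpt1a in heart, Cpt1a and Fasn in liver, Foxo3 and Mstn in muscle and Pdk4 in the tumour, which were not detected on 3 arrays and were not tested. A gene detected on 3 arrays alone was not tested when 1 of them was left out. No probe was matched here to Mki67 and Hk2. A few genes that the rule takes are not reported here.

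For pairs of tissues, the correlation and covariance of fold changes that chance gives with no effect of diet were taken from deviations from the group means, matched by mouse, a test chosen after the data were seen. The steps were tested on simulated data built from the fed means and the spread of each gene, with 200 changed genes, of which 100 were changed 2-fold and 100 changed 4-fold. In heart, on 7957 genes, 50 of the 2-fold and 88 of the 4-fold changes were recovered, with 10 false calls. In muscle, on 7306 genes, 58 and 94 were recovered, with 5 false calls. In liver (6589 genes) and tumour (7395 genes) none of either size was recovered, at the spread measured there. The fit that pools all tissues did not hold its error rate. It made 117 false calls among 194 for the tumour against the mean of the normal tissues (60.3%, 9484 genes), 19 among 49 against heart (8790 genes), 141 among 199 against liver (70.9%, 8313 genes) and 17 among 45 against muscle (8537 genes). With 1 weight per tissue 48.1% of the calls against the mean were still false. The pooled fit was kept because it was fixed beforehand.

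The second letter of the titles (N, R or L) is shared between diets. Alternatives tried were other background corrections, scalings, filters, probe rules, variance models, thresholds, array and tissue weights, blocks, 1 fit of all arrays, and leaving out each array in turn. Chosen after seeing the data were leaving out the 3 arrays with under 20% of probes detected and giving 1 weight per tissue. Array precision is limited by signal over background and by the number of arrays: the share of probes detected ran from 9.13% to 41.1%.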

Results

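Gene expression was profiled in heart, liver, skeletal muscle and a transplanted tumour of Balb/c mice that had fasted for 48 h or had fed freely. The tumour was grown under the skin from 4T1 cells, a mouse mammary carcinoma line. Each of the 8 groups held 3 arrays, 1 per mouse, and the question was how the response of the tumour to food withdrawal compares with that of normal tissues. Signal differed widely between arrays. In muscle 32.2% to 36.4% of probes were detected, and in heart 30.3% to 40.1%. Liver of fasted mice gave 18.4%, 34.7% and 10.3% for replicates 1, 2 and 3, and tumour of fasted mice 26.2%, 38.1% and 9.13%, whereas the fed livers gave 27.5% to 34.5% and the fed tumours 31.5% to 41.1%. Tumour fasted replicate 3 had a median correlation of 0.665 with the other tumour arrays, and liver fasted replicates 1 and 3 had 0.824 and 0.726 with the other liver arrays. The dim arrays all came from fasted mice, and the median residual SD was 0.717 in liver and 0.687 in tumour, against 0.255 in heart and 0.269 in muscle.

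**Figure D1:**
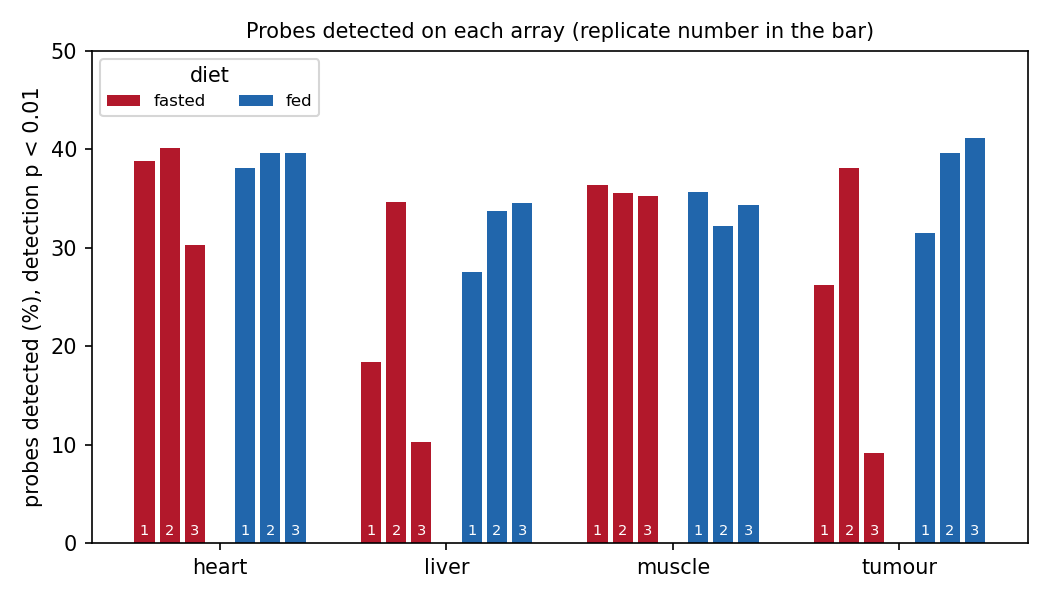
Share of the 25697 probes detected at a detection p below 0.01 (vertical axis, percent) on each of the 24 arrays, by tissue and diet, with the replicate number in each bar. Liver fasted replicates 1 and 3 and tumour fasted replicate 3 lie below 20%, and every muscle array lies above 32%.

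Fasting changed many genes in skeletal muscle. The cell cycle inhibitor gene Cdkn1a (p21) and Sesn1, a sestrin that restrains mTORC1, rose in fasted muscle by 3.56 ± 0.26 and 3.61 ± 0.22 on the log2 scale (SE, n = 3 per diet; adjusted p = 6.61e-06 and 2.00e-06). The muscle ubiquitin ligase genes Trim63 (MuRF1) and Fbxo32 (atrogin-1) rose by 3.39 ± 0.26 and 2.61 ± 0.28. Their regulator Foxo1 rose by 2.49 ± 0.22, and Eif4ebp1, which encodes the translation repressor 4E-BP1, rose by 2.10 ± 0.23. Pdk4, the kinase that shuts off pyruvate dehydrogenase, stood at 13.16 ± 0.44 against 10.22 ± 0.94 in fed muscle (log2, SD; adjusted p = 0.000241). The inositol kinase gene Itpkc rose by 5.15 ± 0.25, the serine protease gene Htra1 by 4.97 ± 0.37, Adamts2 by 4.50 ± 0.28 and the FOXO target Depp1 by 4.42 ± 0.20. Acot1, an acyl-CoA thioesterase gene, rose by 4.57 ± 0.19 and was detected on 2 of 3 fed arrays. Doc2b and Arhgap26 were not detected in fed muscle and were at least 17.8-fold and 15.8-fold higher. The muscle maintenance gene Ky stood at 6.88 ± 0.08 against 12.84 ± 0.33 in fed muscle, and thus fell by 5.96 ± 0.22. The integrin subunit gene Itgb6 fell by 4.47 ± 0.20, Nrep by 4.36 ± 0.35 and the IGF-binding protein gene Igfbp5 by 3.99 ± 0.24. The collagen gene Col24a1 fell by 3.98 ± 0.43, and the carboxylesterase gene Ces1d fell by 3.87 ± 0.37. Fam78a and the phospholipase C gene Plcd4 were not detected in fasted muscle and were at least 25.1-fold and 17.4-fold lower. Ucp3 (0.05 ± 0.29), Angptl4 (0.05 ± 0.27; detected on 2 of 3 fed arrays), Igf1 (-0.56 ± 0.27; detected on 2 of 3 fasted arrays) and the fast myosin gene Myh4 (0.24 ± 0.23) did not pass the threshold. In all 3475 of 7306 genes were called, 1600 higher and 1875 lower. Fasted and fed values did not overlap in 56.9% of genes, where chance gives 10%. With each array scaled to its median in place of quantile normalization, 80.1% of the calls in muscle were higher, against 46.0% here. That scaling put the median of all genes at 0.42 in muscle, -0.48 in heart, -0.81 in liver and -1.40 in tumour (log2).

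FOXO and atrophy, proteasome, and autophagy and lysosome genes passed camera as lists in muscle, each with more members called higher than lower after fasting. Of 14 tested FOXO and atrophy genes 11 rose and 2 fell (11 and 2 adjusted over the list alone), and the insulin receptor substrate gene Irs2 rose by 2.76 ± 0.32. The list had camera adjusted p = 6.90e-05, and adjusted p = 0.224 with an estimated correlation. Of 26 proteasome subunit genes 19 rose and 0 fell (20 and 0 adjusted over the list alone). Psmd11 rose by 1.86 ± 0.25, Psmd8 by 1.85 ± 0.28, Psmd12 by 1.23 ± 0.26 and Psmc4 by 1.20 ± 0.20. For this list the test gave camera adjusted p = 6.90e-05, and adjusted p = 0.222 with an estimated correlation. Of 20 autophagy and lysosome genes 10 rose and 1 fell (10 and 2 adjusted over the list alone), with camera adjusted p = 0.00177, and adjusted p = 0.222 with an estimated correlation. The ATG8 family gene Gabarapl1 rose by 3.66 ± 0.21, Sqstm1 by 1.92 ± 0.26 and the mitophagy receptor gene Bnip3l by 1.67 ± 0.21. The lysosomal protease gene Ctsl rose by 3.43 ± 0.25 and was detected on 1 of 3 fed arrays.

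Lists of stress hormone and amino acid response genes passed camera in muscle too, again with more members called higher than lower. Of 13 glucocorticoid-responsive genes 9 rose and 1 fell (9 and 1 adjusted over the list alone), with camera adjusted p = 0.000900, and adjusted p = 0.288 with an estimated correlation. Among them Fkbp5, a co-chaperone gene of the glucocorticoid receptor, rose by 2.48 ± 0.31, and the metallothionein gene Mt2 rose by 2.74 ± 0.62 and was detected on 1 of 3 fed arrays. Of 18 ATF4 and amino acid response genes 9 rose and 2 fell (9 and 2 adjusted over the list alone), with camera adjusted p = 0.0220, and adjusted p = 0.281 with an estimated correlation. Chac1 rose by 1.62 ± 0.26, Cebpb by 1.51 ± 0.20 and the aminoacyl-tRNA synthetase gene Eprs by 1.38 ± 0.31. Atf3 was not detected in fed muscle and was at least 11.2-fold higher. The ATF4 list lost its call without fasted replicate 2 (camera adjusted p = 0.0870), fasted replicate 3 (0.0860) or fed replicate 1 (0.0572). Without a filter on dim probes Mt2 and Eprs lost their calls (adjusted p = 0.0862 and 0.0520).

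Ribosome biogenesis and translation factor genes leaned upward in fasted muscle as lists, and those of respiration, cell division and the interferon response leaned downward. Of 32 ribosome biogenesis genes 12 rose and 1 fell (12 and 1 adjusted over the list alone), with camera adjusted p = 0.00228, and adjusted p = 0.222 with an estimated correlation. Ltv1 rose by 1.85 ± 0.21, the RNA helicase gene Ddx21 by 1.35 ± 0.21, Rrp12 by 1.24 ± 0.20 and Gnl3 by 1.16 ± 0.19. The 49 cytosolic ribosomal protein genes, a separate list, did not pass, with 4 higher, 1 lower, a median of -0.13 and camera adjusted p = 0.988. Of 30 translation factor genes 13 rose and 2 fell (13 and 2 adjusted over the list alone), with camera adjusted p = 0.0253, and adjusted p = 0.281 with an estimated correlation. Eif1a rose by 1.97 ± 0.27, Eif3a by 1.96 ± 0.29, Eef2 by 1.80 ± 0.44 and Eif3b by 1.38 ± 0.32. Without a filter on dim probes Eef2 and Eif3b lost their calls (adjusted p = 0.0880 and 0.0613). The call of the translation list was lost without fed replicate 2 (camera adjusted p = 0.0645) and on the z-score scale (0.136). Of 58 oxidative phosphorylation genes 20 fell and 0 rose (0 and 20 adjusted over the list alone), with camera adjusted p = 0.00208, and adjusted p = 0.696 with an estimated correlation. By fry its adjusted p was 0.0747, and its median of -0.55 was -0.05 with median scaling and -0.35 without fasted replicate 1. The complex I subunit genes Ndufs8, Ndufv3, Ndufb7 and Ndufc1 fell by 1.27 ± 0.28, 1.25 ± 0.27, 1.20 ± 0.30 and 1.17 ± 0.29. With median scaling these 4 genes lost their calls (adjusted p = 0.179, 0.138, 0.247 and 0.230), and without the filter Ndufb7 and Ndufc1 did (0.0694 and 0.0592).

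Of 9 cell cycle genes tested in muscle 5 fell (0 and 5 adjusted over the list alone, higher and lower), with camera adjusted p = 0.0196, and adjusted p = 0.460 with an estimated correlation. The mitotic kinase gene Aurka and the replication gene Mcm2 fell by 2.87 ± 0.29 and 1.14 ± 0.25, each detected on 1 of 3 fasted arrays, and Ccnd1 fell by 1.26 ± 0.20. The thymidine kinase gene Tk1 was not detected in fasted muscle and was at least 2.55-fold lower. This list lost its call without fasted replicate 2 (camera adjusted p = 0.0742) or fed replicate 3 (0.0523). Of 10 interferon-response genes 8 fell and 1 rose (1 and 8 adjusted over the list alone, higher and lower), with camera adjusted p = 0.0336, and adjusted p = 0.599 with an estimated correlation. Gbp2 fell by 1.31 ± 0.25. Oasl2 and Usp18 were not detected in fasted muscle and were at least 2.41-fold and 2.001-fold lower. The interferon call was lost without fasted replicate 1 (0.0915), without fed replicate 1 (0.223), 2 (0.281) or 3 (0.302), and on the z-score scale (0.0641). Markers of other cell types stood apart in fed replicate 3. The mean of 12 macrophage markers was 6.95 there, against 5.16 and 4.85 in the other fed muscles and 5.02 to 5.14 in the fasted ones (log2). For 9 fibroblast markers it was 7.26, against 6.68 and 6.53 in the other fed and 6.21 to 6.42 in the fasted muscles. Neither list passed camera in muscle (adjusted p = 0.901 and 0.322). The mean of 4 brown fat markers was 10.50 to 10.61 in fasted and 9.44 to 9.54 in fed muscle. Among them, named after their values were seen, Ppargc1a rose by 3.06 ± 0.47, and Cidea was detected on no fed array and was at least 2.98-fold higher. Cox8b (-0.52 ± 0.22) and Cox7a1 (-0.55 ± 0.31) did not pass the threshold, and a list of 4 genes was too short for camera.

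Slow-twitch fibre markers were higher in fasted muscle. Of 8 such genes 7 rose (7 and 0 adjusted over the list alone), with camera adjusted p = 0.000900, and adjusted p = 0.472 with an estimated correlation. The slow troponin genes Tnnc1 and Tnnt1 rose by 3.33 ± 0.80 and 3.26 ± 0.90, and the calcium pump gene Atp2a2 rose by 3.25 ± 0.31. The slow myosin gene Myh7 was not detected in fed muscle and was at least 4.74-fold higher. Csrp3, a muscle LIM protein gene that is not on this list, rose by 5.01 ± 1.02 and was detected on 2 of 3 fed arrays. Without a filter on dim probes Tnnc1, Tnnt1 and Csrp3 lost their calls (adjusted p = 0.103, 0.152 and 0.0673), as they did with a trended robust variance (0.0787, 0.120 and 0.0596). The mean of the 8 markers was 10.77 ± 0.03 in the fasted group and 8.02 ± 1.59 in the fed group (log2, SD, n = 3), where the fed replicates stood at 6.26, 9.35 and 8.45. The 12 fast fibre markers had a median of -0.01, and limma called 0 of them, with 0 at an unadjusted p below 0.05. Their mean was high, at 13.68 to 13.89 in fasted and 13.80 to 13.81 in fed muscle. It differed by -0.04 here, by 0.10 with median scaling and by -1.05 on the z-score scale, so the lack of change depends on the scaling.

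In heart the genes that rose included Acot1, which stood at 11.36 ± 0.42 against 7.71 ± 0.35 in fed hearts (log2, SD, n = 3), and Cdkn1a, which stood at 11.50 ± 0.15 against 8.40 ± 0.41. These were changes of 3.65 ± 0.27 and 3.10 ± 0.23 (SE; adjusted p = 0.000961 for both). The protease inhibitor gene Serpina3n rose by 3.37 ± 0.28, the sphingosine kinase gene Sphk1 by 3.22 ± 0.15, the cysteine dioxygenase gene Cdo1 by 3.18 ± 0.45 and Ccn1 by 2.83 ± 0.39. The lysyl oxidase gene Lox rose by 3.55 ± 0.18 and was detected on 2 of 3 fed arrays. Cd3e, a T-cell receptor component, was not detected in fed hearts and was at least 9.61-fold higher. Nrep fell by 3.40 ± 0.41, the basement membrane collagen gene Col15a1 by 3.26 ± 0.27, the splicing factor gene Srsf7 by 3.14 ± 0.35 and Dnaaf3 by 2.75 ± 0.27, each detected on 2 of 3 fasted arrays. Tuba4a and Slamf9, each detected on 1 of 3 fasted arrays, fell by 3.22 ± 0.30 and 2.87 ± 0.22, and Fam78a fell by 2.82 ± 0.16. Itgb6 was detected on no fasted array and was at least 4.79-fold lower. Among genes chosen beforehand, Pdk4 rose by 1.83 ± 0.45, Fbxo32 by 1.13 ± 0.20, the natriuretic peptide gene Nppb by 1.16 ± 0.25 and the thioredoxin inhibitor gene Txnip by 1.04 ± 0.24. Angptl4 (0.04 ± 0.48; detected on 2 of 3 fasted arrays), the glucose transporter gene Slc2a4 (-0.17 ± 0.37), Igf1 (-0.37 ± 0.17) and Nppa (-0.05 ± 0.63) did not pass the threshold. Without fasted replicate 1 or fed replicates 1 or 3 Pdk4 lost its call (adjusted p up to 0.0809). Without fasted replicate 1 or fed replicates 1 or 2 Txnip lost its call (up to 0.0806). Nppb lost its call without fed replicates 1 or 3 (up to 0.0794), and Fbxo32 without fed replicate 1 (0.0588). On the z-score scale Pdk4, Fbxo32, Nppb and Txnip were not called (adjusted p = 0.1005, 0.148, 0.411 and 0.227).

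In all 1693 of 7957 genes tested in heart were called, 760 higher and 933 lower. Fasted and fed values did not overlap in 45.0% of genes, where chance gives 10%. The count was 882 without fasted replicate 1 and 442, 595 and 412 without fed replicates 1, 2 and 3. On the z-score scale it was 186, and with median scaling limma called 0 genes, with 306 at an unadjusted p below 0.05. Hepatocyte transcripts were high in fed replicate 3, where Apoa2 read 9.71 against 4.54 and 4.39 in the other fed hearts. The atrial light chain gene Myl7 read 4.60, 12.15 and 11.47 in fed replicates 1, 2 and 3, and 11.93, 8.29 and 7.09 in the fasted ones. Apoa2 and Myl7 were named after their values were seen. The mean of 9 fibroblast markers was 7.34 to 7.68 in fasted and 7.93 to 8.30 in fed hearts, and the list did not pass camera (adjusted p = 0.443). For 6 T and NK cell markers it was 5.79 to 6.16 against 5.41 to 5.52, and for 6 erythroid markers 7.58 to 8.05 against 8.07 to 8.14. The T and NK markers include Cd3e, described above, and 2 of them were tested in heart. The rise of Cd3e alone is large enough to give the difference of 0.53 in their mean.

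Of 12 glucocorticoid-responsive genes tested in heart 7 rose and 0 fell (10 and 0 adjusted over the list alone), with camera adjusted p = 7.70e-05, and adjusted p = 0.478 with an estimated correlation. Fkbp5 rose by 1.92 ± 0.16. Mt2, detected on 2 of 3 fasted and 1 of 3 fed arrays, rose by 1.64 ± 0.37 and lost its call without fed replicates 1 or 2 (adjusted p up to 0.0885). Of 13 FOXO and atrophy genes in heart 8 rose and 2 fell (10 and 2 adjusted over the list alone), with camera adjusted p = 0.00209, and adjusted p = 0.478 with an estimated correlation. Irs2 rose by 1.89 ± 0.23. The ubiquitin ligase gene Fbxo30, detected on 1 of 3 fasted arrays, fell by 2.50 ± 0.25, and the transcriptional repressor gene Bcl6 fell by 1.40 ± 0.25. Of 15 interferon-response genes in heart 7 fell and 0 rose (0 and 8 adjusted over the list alone, higher and lower), with camera adjusted p = 0.00209, and adjusted p = 0.478 with an estimated correlation. Oasl2, detected on 1 of 3 fasted arrays, fell by 2.72 ± 0.24. Usp18, detected on 2 of 3 fasted arrays, fell by 1.97 ± 0.26, and Gbp2 fell by 1.24 ± 0.21. Gbp2 lost its call without fed replicate 3 (adjusted p = 0.0506). With the mean over its probes Gbp2 differed by -0.38 and was not called (limma adjusted p = 0.0626). Mt2, Bcl6 and Gbp2 were not called on the z-score scale (0.163, 0.122 and 0.122).

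Translation factor genes leaned upward in heart, with 7 of 30 higher and 0 lower (7 and 0 adjusted over the list alone). Their median was 0.23, but -0.36 with median scaling, and the list had camera adjusted p = 0.0136, and adjusted p = 0.478 with an estimated correlation. It lost its call with median scaling (adjusted p = 0.349) and on the z-score scale (0.0568). Eif1a rose by 1.63 ± 0.16, Eif5 by 1.35 ± 0.18, Eif3b by 0.79 ± 0.20 and Pabpc1 by 0.78 ± 0.19. With the mean over a gene's probes Eif3b and Pabpc1 differed by 0.43 and 0.37 and were not called (limma adjusted p = 0.0719 and 0.102). Of 58 oxidative phosphorylation genes 3 fell. By limma 0 did so adjusted over the list alone, with 12 at an unadjusted p below 0.05. Their median was -0.32, but 0.00384 on the z-score scale, where the adjusted p was 0.919, and the list had camera adjusted p = 0.0135, and adjusted p = 0.859 with an estimated correlation. With median scaling the median was -0.94, and by fry the adjusted p was 0.138. Ndufb7, Ndufs8 and Atp5d fell by 0.73 ± 0.17, 0.70 ± 0.21 and 0.58 ± 0.16. The respiration list lost its call without fasted replicate 1 (camera adjusted p = 0.0991) or fasted replicate 3 (0.0525). Without fed replicate 1, 2 or 3 or fasted replicate 1, Ndufb7, Ndufs8, Atp5d and Pabpc1 lost their calls (adjusted p up to 0.121, 0.173, 0.182 and 0.123). Eif3b did so without fed replicate 1, 2 or 3 or fasted replicate 2 (up to 0.106). Eif5, Eif3b, Pabpc1, Ndufb7, Ndufs8 and Atp5d were not called on the z-score scale (0.248, 0.385, 0.158, 0.122, 0.424 and 0.417).

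In liver, genes of sterol and fat synthesis stood lower after fasting as lists, with few members called. Of 19 cholesterol synthesis genes 4 fell and 0 rose (0 and 16 adjusted over the list alone, higher and lower). Their median was -2.73, with camera adjusted p = 1.08e-10, and adjusted p = 0.416 with an estimated correlation. Farnesyl diphosphate synthase (Fdps) and Dhcr7, each detected on 1 of 3 fasted arrays, fell by 4.46 ± 0.43 and 3.38 ± 0.47. Sqle and Msmo1 were detected on no fasted array and were at least 3.84-fold and 2.35-fold lower. Of 14 lipogenic genes 3 fell and 0 rose (0 and 9 adjusted over the list alone, higher and lower), with a median of -1.44 and camera adjusted p = 5.74e-05, and adjusted p = 0.416 with an estimated correlation. The medians of these 2 lists were -2.46 and -2.62 with median scaling and -1.69 and -1.77 on the z-score scale. The mean of 9 adipocyte markers was 7.14 to 7.63 in fasted and 6.10 to 6.43 in fed livers, a difference of 1.15, or 0.21 with median scaling. The 3 of them that were tested, Lpl (1.48 ± 0.47), Pnpla2 (1.64 ± 0.53) and Plin4 (0.96 ± 0.52), did not pass the threshold (adjusted p = 0.167, 0.173 and 0.341) and were named after their values were seen. Thrsp, detected on 1 of 3 fasted arrays, fell by 5.41 ± 0.71. The fatty acid elongase gene Elovl6 and the transcription factor gene Srebf1 were detected on no fasted array and were at least 1.97-fold and 1.37-fold lower. The corticosteroid-binding globulin gene Serpina6 fell by 6.26 ± 0.58, the creatine synthesis gene Gamt by 5.82 ± 0.50 and Inmt by 5.28 ± 0.65, each detected on 1 of 3 fasted arrays. Hdhd3 was detected on no fasted array and was at least 2.42-fold lower. The adrenergic receptor gene Adra2a stood at 11.86 ± 1.66 against 5.82 ± 0.63 in fed liver (log2, SD, n = 3; adjusted p = 0.0317). Ctsl rose by 3.98 ± 0.67 and the lipid droplet gene Hilpda by 3.31 ± 0.41, each, like Adra2a, detected on 2 of 3 fed arrays. Cd14 rose by 3.87 ± 0.45, Nfkbib by 3.66 ± 0.46, Acot1 by 3.51 ± 0.44 and the ER-phagy receptor gene Retreg1 by 2.80 ± 0.44. The activin antagonist gene Fst was detected on no fed array and was at least 8.53-fold higher. Several known fasting genes did not pass the threshold: G6pc (1.77 ± 0.52), Igf1 (-1.17 ± 0.56), Scd1 (-1.99 ± 0.42) and Angptl4 (0.52 ± 0.61). Nor did some that were not detected on every array: Pck1 (0.06 ± 0.78; 2 of 3 fasted arrays), Fgf21 (-1.26 ± 0.48; 1 of 3 fasted arrays), Pdk4 (2.89 ± 0.87; 2 of 3 fed arrays) and Igfbp1 (2.75 ± 1.14; 2 of 3 arrays in each group).

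In all 51 of 6589 genes were called in liver, 9 higher and 42 lower, and 1271 had an unadjusted p below 0.05. Fasted and fed values did not overlap in 28.2% of genes, where chance gives 10%, and the median of all genes was -0.39. On the z-score scale 22 genes were called, 0% of them higher, against 17.6% here. With median scaling limma called 0 genes, with 296 at an unadjusted p below 0.05. Requiring detection on all 6 arrays made the share higher 57.4%. The count turned on which arrays were used. It was 0 by limma without fasted replicate 1 or without fed replicate 1, 2 or 3, 22 without fasted replicate 3, and 1799 without fasted replicate 2, the only fasted liver with over 20% of probes detected. Genes detected on 3 arrays alone (Sqle, Msmo1, Hdhd3, Elovl6, Srebf1 and Fst) were not tested when 1 of those 3 was left out. Sqle, Msmo1 and Hdhd3 lost their calls without fasted replicate 1 (adjusted p = 0.104 for each). Elovl6 and Srebf1 did so without fasted replicates 1 or 3 (up to 0.107 and 0.112). Acot1, Adra2a, Cd14, Hilpda, Fdps, Gamt, Serpina6, Inmt and Sesn1 did so without fasted replicate 1 or fed replicate 1, 2 or 3 (up to 0.403), and Fst without fed replicate 1, 2 or 3 (up to 0.318). Ctsl, Dhcr7, Nfkbib, Retreg1, Thrsp and Tk1 did so without any array other than fasted replicate 2 (up to 0.403).

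FOXO and atrophy genes stood higher in fasted liver, with a median of 1.82 over 12 genes and camera adjusted p = 2.71e-06, and adjusted p = 0.644 with an estimated correlation. Of them Sesn1 was called, with a rise of 2.78 ± 0.44 (5 and 0 adjusted over the list alone). With the mean over its probes Sesn1 differed by 1.51 and was not called (limma adjusted p = 0.126). Nor was it called without a filter on dim probes (0.0532) or on the z-score scale (0.190). Interferon-response genes stood lower, with a median of -1.28 over 13 genes and camera adjusted p = 0.00241, and adjusted p = 0.416 with an estimated correlation. By limma 0 members were called (0 and 6 adjusted over the list alone, higher and lower), with 7 at an unadjusted p below 0.05. Irf7 and Isg15, named after their values were seen, were detected on 3 fed and 0 fasted arrays (adjusted p = 0.0553 and 0.0631). This call was lost without fasted replicate 2 (camera adjusted p = 0.184) or fed replicates 1 (0.101), 2 (0.226) or 3 (0.150). Cell cycle genes stood lower, with a median of -0.94 over 12 genes and camera adjusted p = 0.0281, and adjusted p = 0.740 with an estimated correlation. Tk1, detected on 1 of 3 fasted arrays, fell by 3.22 ± 0.44 (0 and 3 adjusted over the list alone, higher and lower). With the mean over its probes Tk1 differed by -1.42 and was not called (limma adjusted p = 0.124). Nor was it called without a filter on dim probes (0.0530) or on the z-score scale (0.117). The cell cycle call was lost without fasted replicate 2 (0.638) or fed replicates 1 (0.149) or 2 (0.246). The medians of these FOXO, interferon and cell cycle lists were 0.56, -1.39 and -0.97 with median scaling and 1.13, -0.63 and -0.41 on the z-score scale. Without the dim arrays the cell cycle median was -1.49. By fry their adjusted p was 0.204, 0.00502 and 0.157. Among 10000 random lists matched on the level in fed livers the medians lay at percentiles 100, 1.22 and 6.04, so that of the cell cycle list was not within the lowest 5%. The lists had already passed camera on the same fold changes, and the draws left out the correlation among members. The percentiles are therefore not separate support.

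The liver's ribosome biogenesis genes had a median of 0.13 over 28 genes, but -0.41 with median scaling, with camera adjusted p = 0.00855, and adjusted p = 0.459 with an estimated correlation. Its glucocorticoid-responsive genes had a median of 0.19 over 13 genes, but -0.83 with median scaling and -0.08 on the z-score scale, with camera adjusted p = 0.0166, and adjusted p = 0.681 with an estimated correlation. Erythroid markers had a median of 1.09 over 5 genes, but -0.14 with median scaling, with camera adjusted p = 0.0472, and adjusted p = 0.681 with an estimated correlation. By limma 0 members of these 3 lists were called over all genes, with 4, 3 and 2 at an unadjusted p below 0.05, and 0, 3 and 0 were higher adjusted over the list alone. The ribosome list lost its call without fasted replicate 2 (camera adjusted p = 0.0722). The glucocorticoid list lost it without fasted replicates 2 (0.316) or 3 (0.0590), with median scaling (0.229) and on the z-score scale (0.0679). The erythroid list lost it without fasted replicates 1 (0.0533) or 3 (0.166) or fed replicate 1 (0.119), and with median scaling (0.0744). Without the dim arrays, a fit chosen after seeing the data that holds 1 fasted liver array, assumed to vary like the fed ones, its adjusted p was 0.886. In that fit the medians of the 3 lists were 0.40, 0.98 and 0.49. The ribosome median was 0.33, 0.07 and 0.43 without fasted replicates 1, 2 and 3 and 0.25 without fed replicate 3. The glucocorticoid median was 0.49, 0.06 and 0.42 without the same 3 fasted arrays in turn, and 0.37 and 0.46 without fed replicates 2 and 3. The erythroid median was 0.41 without fasted replicate 3. By fry their adjusted p was 0.566, 0.323 and 0.352, and among the matched random lists their medians lay at percentiles 98.79, 95.55 and 99.62. These percentiles have the same limits as those of the other liver lists and are not separate support.

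No gene passed the threshold in the tumour. Of 7395 genes tested limma called 0, with 618 at an unadjusted p below 0.05 and a smallest adjusted p of 0.562. Fasted and fed values did not overlap in 19.7% of genes, where chance gives 10%, and the median of all genes was -0.37. Simulated 4-fold changes in 100 genes, set beside 2-fold changes in 100 others, were not recovered at this spread. A response of that extent could thus be missed by this test. The simulation does not cover a response of more genes. In liver it recovered 0 changes too, yet 51 genes were called there. On the higher side the lowest p-values belonged to Map1b (2.54 ± 0.51), Sox21 (3.59 ± 0.87), Erdr1 (1.62 ± 0.41), Itgb6 (1.91 ± 0.48; detected on 2 of 3 arrays in each group) and Zfp91 (1.40 ± 0.38; detected on 2 of 3 fasted arrays). On the lower side they belonged to Ifi27l2a (-3.37 ± 0.52) and Adgrg5 (-2.44 ± 0.43), each detected on 1 of 3 fasted arrays, and to 3 genes detected on no fasted array. These were the chemokine receptor gene Cx3cr1, LOC100048556 and Arhgap4, at least 2.86-fold, 2.37-fold and 1.19-fold lower. All 10 had an adjusted p of 0.562. Among genes chosen beforehand, differences below their SE were seen for Igf1r (-0.06 ± 0.47), Cat (0.04 ± 0.36), Cdkn1a (0.04 ± 0.43), Asns (-0.01 ± 0.51) and Myc (0.26 ± 0.60), each detected on 2 of 3 fasted arrays, and for Sod2 (0.09 ± 0.46), Slc2a1 (0.07 ± 0.42) and Krt18 (0.32 ± 0.43). For Cdkn1a 2 other probes pointed the other way. Txnip (-1.93 ± 0.70), Trib3 (-1.05 ± 0.93), Angptl4 (0.75 ± 0.49) and Hmox1 (-0.76 ± 0.65) differed by more than their SE but were not called. Of these Hmox1 was detected on 1 of 3 fasted arrays and the others on 2, and 1 of 2 other Trib3 probes pointed the other way. Ccnd1 (-0.62 ± 0.54) and S100a8 (1.77 ± 1.11) were not called either. Igf1 was detected on all 3 fed arrays (5.55 ± 0.25, log2, SD) and on no fasted array, where its value was 6.35 ± 1.69.

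Markers of macrophages, vessels and fibroblasts stood lower in fasted tumours as lists, with 0 members called by limma over all genes. At an unadjusted p below 0.05 were 7 macrophage, 6 endothelial, 5 fibroblast and 7 extracellular matrix genes. The members given here were named after their values were seen. Macrophage markers had a median of -1.93 over 11 genes (0 and 5 adjusted over the list alone, higher and lower), with camera adjusted p = 0.00250, and adjusted p = 0.535 with an estimated correlation. The complement genes C1qa, C1qb and C1qc differed by -3.12, -1.9996 and -3.16 and were detected on 1, 2 and 2 of 3 fasted arrays. Endothelial markers had a median of -1.38 over 8 genes (0 and 5 adjusted over the list alone, higher and lower), with camera adjusted p = 0.00250, and adjusted p = 0.535 with an estimated correlation. The tight-junction gene Cldn5 and the cadherin gene Cdh5 differed by -2.56 and -1.29, each detected on 1 of 3 fasted arrays. Fibroblast markers had a median of -1.91 over 7 genes (0 and 5 adjusted over the list alone, higher and lower), with camera adjusted p = 0.0198, and adjusted p = 0.535 with an estimated correlation. Among them Col1a1 and Pdgfrb differed by -3.16 and -1.91, each also detected on 1 fasted array. Extracellular matrix genes had a median of -1.40 over 19 genes (0 and 0 adjusted over the list alone), with camera adjusted p = 0.00256, and adjusted p = 0.647 with an estimated correlation. Without fasted replicate 1 these 4 lists lost their calls (camera adjusted p = 0.0968, 0.0908, 0.238 and 0.485). The fibroblast list also lost its call without fasted replicate 2 (0.0519) or fed replicate 1 (0.0561), and the endothelial list with median scaling (0.0845). The 4 medians were -1.92, -2.08, -2.24 and -2.63 with median scaling and -1.05, -1.03, -1.13 and -1.11 on the z-score scale. Without fasted replicate 1 the macrophage and matrix medians were -1.20 and -0.65, and without fasted replicate 2 the endothelial and matrix medians were -2.13 and -2.18. By fry, which does not set a list against other genes, 0 of the 32 tumour lists passed, with adjusted p = 0.261, 0.261, 0.261 and 0.556 for these 4. The haemoglobin gene Hba-a1, an erythroid marker named after its values were seen, read 13.30, 11.81 and 11.32 in fasted replicates 1, 2 and 3 and 11.17, 8.45 and 9.15 in the fed ones (adjusted p = 0.562). The mean of 6 erythroid markers was 7.51, 6.18 and 5.69 against 5.73, 5.19 and 5.33, with 1 marker tested, so the list was not.

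Other tumour lists passed camera, some with medians whose direction depended on the scaling. Neutrophil markers had a median of 1.101 over 7 genes, but -0.38 with median scaling (camera adjusted p = 0.00250, and adjusted p = 0.535 with an estimated correlation). Acute phase proteins had a median of 1.40 over 5 genes, but -0.31 with median scaling (camera adjusted p = 0.00476, and adjusted p = 0.535 with an estimated correlation). Epithelial markers had a median of 0.32 over 9 genes, but -1.11 with median scaling (camera adjusted p = 0.0109, and adjusted p = 0.535 with an estimated correlation). Glucocorticoid-responsive genes had a median of 0.17 over 11 genes, but -1.47 with median scaling (camera adjusted p = 0.0396, and adjusted p = 0.647 with an estimated correlation). Oxidative phosphorylation genes (-0.86 over 53 genes) and cholesterol synthesis genes (-0.85 over 13 genes) stood lower under each scaling, at -2.22 and -1.65 with median scaling and -0.67 and -0.71 on the z-score scale. Against the fed mean the respiration median was -0.11, -0.55 and -1.78 in fasted replicates 1, 2 and 3. It was -1.35 without replicate 1 and -0.27 without the dim replicate 3. With all arrays the respiration list had camera adjusted p = 0.00476, and adjusted p = 0.870 with an estimated correlation. The cholesterol synthesis list with all arrays had camera adjusted p = 0.0130, and adjusted p = 0.647 with an estimated correlation. By limma 0 members of these 6 lists were called over all genes, with 1, 1, 1, 1, 5 and 4, in the order given, at an unadjusted p below 0.05. Adjusted over the list alone 1 cholesterol synthesis gene was lower and 0 of the others were called. Without fasted replicate 1 the epithelial (0.0567), cholesterol (0.0968) and glucocorticoid (0.0968) lists lost their calls (camera adjusted p). Without fasted replicate 2 the respiration (0.215), cholesterol (0.0519) and glucocorticoid (0.233) lists did. Without fasted replicate 3 the neutrophil (0.0703) and cholesterol (0.0687) lists did. Without fed replicate 2 the cholesterol (0.143) and glucocorticoid (0.173) lists did, and without fed replicate 3 the cholesterol list (0.135). Without the dim arrays, a fit chosen after seeing the data, the neutrophil (0.0718) and cholesterol (0.0713) lists lost theirs. Median scaling ended the calls of the epithelial (0.390), cholesterol (0.211) and glucocorticoid (0.596) lists, and the z-score scale that of the respiration list (0.104). On the z-score scale the neutrophil and acute phase medians were 0.51 and 0.66. Without fed replicate 2 the neutrophil, acute phase, epithelial and glucocorticoid medians were 0.72, 0.91, 0.60 and 0.06. The epithelial median was 0.12, 0.49 and 0.60 without fasted replicates 1, 2 and 3. The glucocorticoid median was 0.06 without fasted replicate 1 and 0.62 without replicate 3, and the neutrophil median was 1.90 without replicate 2. Among random lists matched on the level in fed tumours the 6 medians lay at percentiles 100, 99.98, 99.74, 98.8, 0 and 2.38. As in liver, lists that had passed camera were set against genes drawn independently, so the percentiles are not separate support. By fry the adjusted p of the 6 lists ran from 0.556 to 0.818.

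The fasting effect in the tumour was set against the mean effect in the 3 normal tissues. Sesn1 and Acot1, higher in all 3 fasted normal tissues, had a lower effect in the tumour, with differences between effects of -4.68 and -3.87 (adjusted p = 1.68e-05 and 4.09e-05). Their own differences in the tumour were -2.13 and 0.05. Tumour Sesn1 was detected on 1 of 3 fasted and 3 fed arrays. Tumour Acot1 was detected on 1 array in each group, so its difference there compares values that mostly lay at background. The effect was also lower in the tumour for Ctsl (-4.25), Irs2 (-3.37), Lat2 (-3.31), Txnip (-3.28) and Klhl21 (-3.08), each detected on 2 of 3 fasted tumour arrays. It was higher for G0s2, an inhibitor gene of the lipase ATGL, which fell in the normal tissues and was detected on 1 fasted and 0 fed tumour arrays, and for Ranbp3l and Ptprd. These 3 were not detected in 1 or more groups, and their differences were at least 3.28, 3.37 and 2.88 (log2). For 6 other genes that passed, groups without a detected array leave the difference without a size. These were Itgb6, Ky, the prolactin receptor gene Prlr, Lsmem1 and Caln1, with adjusted p = 4.68e-06, 0.0143, 0.0229, 0.00862 and 0.0367, and Cx3cr1 (0.000757). Itgb6 differed by 1.91 in tumour and -4.47 in muscle, and no array of liver detected it. Prlr, Lsmem1, Ptprd and Caln1 were detected on no fed tumour array, Ranbp3l on 1 and Ky on 2. In Ky, Ranbp3l, Prlr, Lsmem1, Ptprd and Caln1 the fasted tumours followed the dimness of the array. Prlr read 11.32 on the dim fasted replicate 3, 7.56 on replicate 1 and 5.51 on the bright replicate 2, against 4.38 to 4.65 in fed tumours. On the lower side Sesn1 read 4.24, 5.59 and 6.75 on the same arrays, against 7.43 to 7.81 in fed tumours. Ctsl read 4.33, 7.50 and 7.51, against 7.44 to 7.54, and Irs2 read 4.56, 9.43 and 8.22, against 8.32 to 8.60. Klhl21 and Txnip were also lowest on replicate 3, but Lat2 was highest there. The tumour falls of Ctsl and Irs2 thus rest on the dim array. Ky lost its call without tumour fed replicate 2 (adjusted p = 0.0690). Prlr and Lat2 did so without tumour fed replicates 2 or 3 (up to 0.0742 and 0.0789), and Ranbp3l and Klhl21 without tumour fed replicate 1, 2 or 3 (up to 0.0852 and 0.0867). Caln1 and Irs2 lost theirs without any fed tumour, fed liver, fed heart or fasted muscle array, heart fasted replicates 1 or 2, or muscle fed replicates 1 or 2 (up to 0.104 and 0.109). Irs2 did so also without heart fasted replicate 3 or muscle fed replicate 3. Without the 3 dim arrays, which leaves 1 fasted liver array, all 16 genes passed, and with 1 weight per tissue 4 did, namely Sesn1, Acot1, Itgb6 and Cx3cr1. Both fits were chosen after seeing the data. Without the dim arrays the differences of Klhl21 and Irs2 were -1.59 and -2.09, and the fitted ones of Ranbp3l (2.82) and Ptprd (2.47) lay under the bounds given. Without tumour fasted replicate 3 alone they were -1.92 for Klhl21 and -1.95 for Irs2. With array weights Klhl21, Irs2 and Txnip stood at -1.94, -1.56 and -1.88. With the mean over a gene's probes Sesn1 and Acot1 stood at -3.01 and -2.07, and Ranbp3l and Ptprd at 2.53 and 1.85. The fitted differences of G0s2, Ranbp3l and Ptprd were 2.08, 2.33 and 1.72 on the z-score scale. On the z-score scale Ranbp3l (0.0950), Prlr (0.0528) and Caln1 (0.0871) lost their calls, and with median scaling all but Ky did (from 0.0545 to 0.378).

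**Figure D2:**
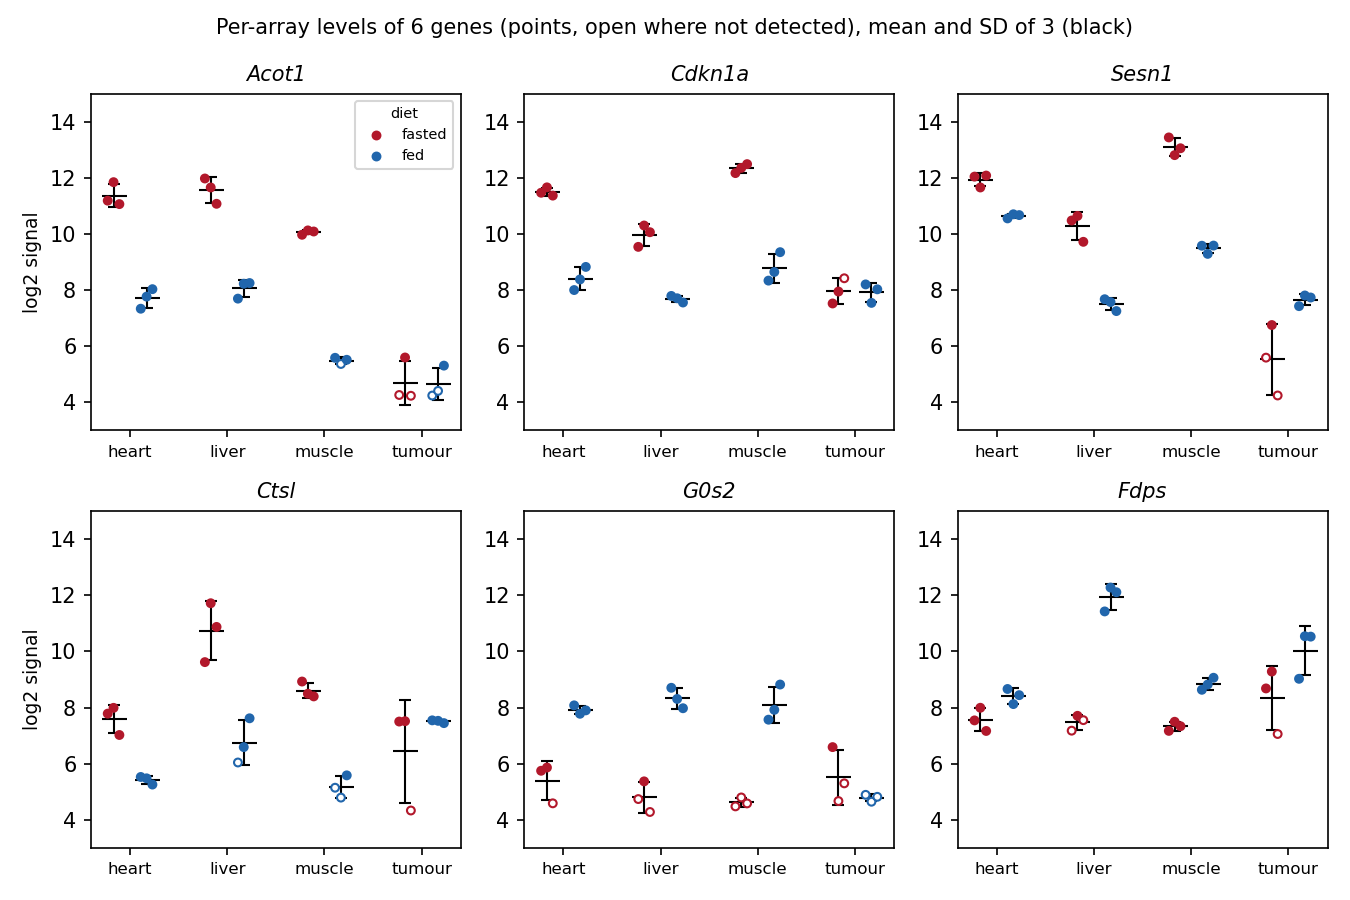
Normalized log2 signal (vertical axis) of Acot1, Cdkn1a, Sesn1, Ctsl, G0s2 and Fdps in the 4 tissues of fasted (red) and fed (blue) mice, 1 point per array, open where the probe was not detected, with the mean and SD of 3 in black. Acot1 was higher in fasted heart, liver and muscle by 3.65, 3.51 and 4.57 (log2), and in the tumour 1 array of each diet detected it.

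By count, the fasting effect differed between the tumour and the mean of the normal tissues for 217 of 9484 genes, 80 higher and 137 lower in the tumour. Against heart it differed for 40 of 8790 genes (17 and 23), against liver for 387 of 8313 (253 and 134) and against muscle for 555 of 8537 (208 and 347). On simulated data this pooled test made 60.3%, 38.8%, 70.9% and 37.8% false calls among its calls in these 4 comparisons. With median scaling 1, 9, 10 and 184 genes were called. Of these 100%, 88.9%, 100% and 20.1% were higher in the tumour, against 36.9%, 42.5%, 65.4% and 37.5% here. On the z-score scale 62.8% of the calls against heart were higher. Leaving out tumour fasted replicate 2, the bright one, gave 1326 (mean), 548 (heart), 870 (liver) and 1417 (muscle). Other single arrays also moved the counts by over 1.5 times. Against the mean these were tumour fasted replicate 1 (338) and tumour fed replicates 1 (118), 2 (54), 3 (73). In liver they were fasted replicates 1 (335), 2 (626), 3 (504) and fed replicates 1 (138), 2 (124), 3 (132). In heart they were fasted replicate 1 (135) and fed replicates 1 (130), 2 (132), 3 (116). In muscle they were fasted replicates 1 (130), 2 (141), 3 (138) and fed replicates 1 (124) and 2 (120). Against heart they were heart fasted replicates 1 (18) and 3 (15), heart fed replicates 1 (17), 2 (16), 3 (12), tumour fasted replicate 3 (61) and tumour fed replicates 1 (25), 2 (13), 3 (14). Against liver they were liver fed replicates 1 (247), 2 (178), 3 (179), liver fasted replicate 2 (1354) and tumour fed replicates 1 (237), 2 (208), 3 (249). Against muscle they were muscle fasted replicates 1 (224), 2 (318), 3 (344), muscle fed replicates 1 (298), 2 (277), 3 (365) and tumour fed replicates 2 (311) and 3 (337).

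Heart and muscle shared much of their response to fasting. Of 6907 genes tested in both, 470 rose in both, where independent lists of these sizes give 149. In both 562 fell, where independent lists give 198. The fold changes correlated across genes with r = 0.651, where genes are not independent replicates and deviations of the same mice alone give 0.0797, and 23 of 1055 genes called in both went opposite ways. Each tissue was compared within itself, so no control array is shared, although the same mice gave both tissues. Liver shared 6 rises and 14 falls with heart, and 5 rises and 17 falls with muscle. Acot1, Nfkbib, Ctsl, Retreg1 and Sesn1 rose in all 3 normal tissues. Tmem25, G0s2, Mmp15, Srsf7, Gamt, Ifi27l2a, Ly6e, Lrtm1, Fdps and Mmab fell in all 3. These 15 were named after their values were seen, as the complete set. Of the rises, Acot1 was lowest in liver, at 3.51, and Sesn1 lowest in heart, at 1.28. In heart Fdps fell by 0.84 and Mmab by 0.77. No gene was called in all 4 tissues, since limma called 0 in the tumour, where 618 had an unadjusted p below 0.05. The tumour's fold changes correlated across genes with those of heart (r = 0.257), liver (0.392) and muscle (0.149). Deviations from the group means, matched by mouse, give r of 0.0964, 0.338 and -0.0446 with no effect of diet. The covariances were 0.13, 0.334 and 0.111, against 0.0164, 0.145 and -0.00747 with no effect. The dim arrays of liver and tumour were all of fasted mice, and the dimmest of each came from the same mouse, as read from the titles. The dimmest heart array, fasted replicate 3, carried the letters of that mouse too. It had 30.3% of probes detected and an array weight of 0.141, the lowest in heart. In at least 2 tissues 471 genes rose and 573 fell, 1044 in total. This total was 616 without heart fasted replicate 1 and 336, 443 and 317 without heart fed replicates 1, 2 and 3. With median scaling it was 0, since limma then called 0 genes in heart, with 306 at an unadjusted p below 0.05.

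**Figure D3:**
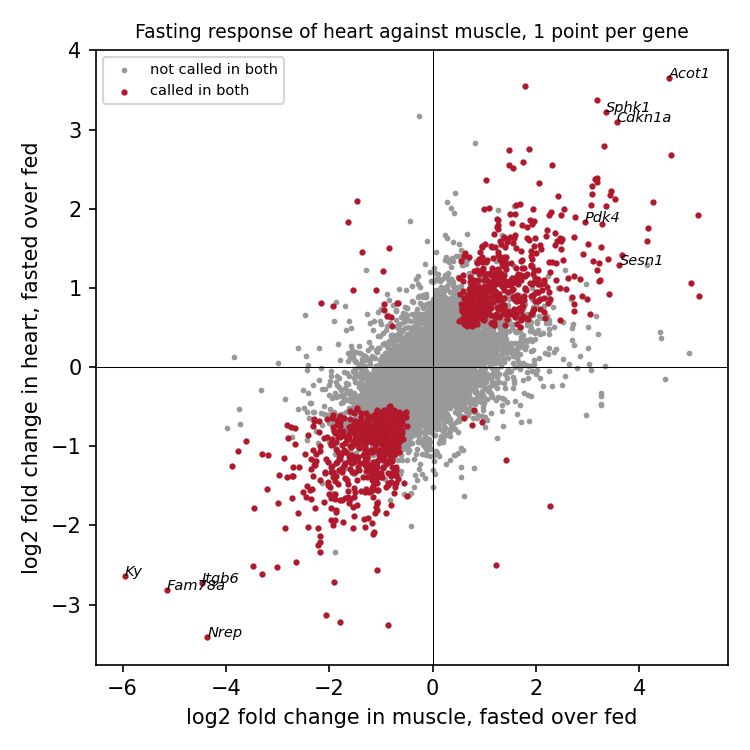
Log2 fold change, fasted over fed, in muscle (horizontal axis) and in heart (vertical axis) for the 6907 genes tested in both, 1 point per gene, with genes called in both tissues in red. Of the 1055 genes called in both, 470 lie in the upper right and 562 in the lower left quadrant.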

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

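The tests of slow fibre shares, of a rise of slow fibre genes, of tumour fasted replicate 3 on the stromal lists and of the count of list medians below the fed mean were chosen after the results were seen; the others were set down before. Beside each tissue's own fasting effect, the difference between that effect and the tumour's was tested for the named genes, and those past the threshold are given here as tumour minus normal tissue on the log2 scale. A gene that no array of a group detected has only an upper limit there. Its difference is then given as a bound where that limit sets one, and otherwise by its adjusted p alone. Against heart it was higher in the tumour for Oasl2 (2.43), as a bound for Itgb6 (4.17 or more), and without a size for Tuba4a (adjusted p = 0.00121) and Dnaaf3 (adjusted p = 0.00121). It was lower than in heart for Acot1 (-3.61) and Cdkn1a (-3.06), as a bound for Cd3e (-1.87 or less) and Cdo1 (-1.54 or less), and without a size for Cx3cr1 (adjusted p = 0.0220) and Adgrg5 (adjusted p = 0.0336). Against liver it was higher in the tumour for Gamt (5.08), Tk1 (2.79), Fdps (2.77) and Cat (2.04), as a bound for Msmo1 (0.44 or more), and without a size for Serpina6 (adjusted p = 1.60e-07), Hdhd3 (adjusted p = 4.97e-05), Thrsp (adjusted p = 0.000237), Dhcr7 (adjusted p = 0.00104), Srebf1 (adjusted p = 0.00108), Inmt (adjusted p = 0.00504) and Map1b (adjusted p = 0.0193). It was lower than in liver for Adra2a (-6.09), Ctsl (-5.04), Sesn1 (-4.91), Txnip (-4.55), Cd14 (-4.18), Acot1 (-3.46), Hilpda (-2.88) and Cdkn1a (-2.24), as a bound for Fst (-2.72 or less), and without a size for Cx3cr1 (adjusted p = 0.00133) and LOC100048556 (adjusted p = 0.00422). Against muscle it was higher in the tumour for Ky (8.86), Itgb6 (6.38), Col24a1 (4.88), Igfbp5 (4.45) and Nrep (4.01), as a bound for Oasl2 (0.98 or more), and without a size for Plcd4 (adjusted p = 1.56e-08), Fam78a (adjusted p = 8.79e-05), Ces1d (adjusted p = 0.00268) and Sox21 (adjusted p = 0.0118). It was lower than in muscle for Adamts2 (-5.90), Sesn1 (-5.74), Itpkc (-5.59), Depp1 (-5.15), Atp2a2 (-4.97), Htra1 (-4.57), Acot1 (-4.52), Ctsl (-4.49), Foxo1 (-3.98), Irs2 (-3.79), Tnnc1 (-3.56), Fkbp5 (-3.52), Cdkn1a (-3.52), Gabarapl1 (-3.35), Ltv1 (-2.92), Eif4ebp1 (-2.41), Eif1a (-2.09), Rrp12 (-1.76), Cebpb (-1.71) and Psmc4 (-1.58), as a bound for Tnnt1 (-1.36 or less), and without a size for Doc2b (adjusted p = 1.71e-08), Trim63 (adjusted p = 1.16e-05), Cx3cr1 (adjusted p = 0.000700), Myh7 (adjusted p = 0.00266), Arhgap26 (adjusted p = 0.00266), Csrp3 (adjusted p = 0.010), Adgrg5 (adjusted p = 0.0110) and LOC100048556 (adjusted p = 0.0174). Against the mean of the 3 normal tissues it was higher in the tumour as a bound for Ranbp3l (3.37 or more), G0s2 (3.28 or more) and Ptprd (2.88 or more), and without a size for Itgb6 (adjusted p = 4.68e-06), Lsmem1 (adjusted p = 0.00862), Ky (adjusted p = 0.0143), Sox21 (adjusted p = 0.0148), Prlr (adjusted p = 0.0229), Map1b (adjusted p = 0.0363) and Caln1 (adjusted p = 0.0367). It was lower than in that mean for Sesn1 (-4.68), Ctsl (-4.25), Acot1 (-3.87), Irs2 (-3.37), Lat2 (-3.31), Txnip (-3.28), Klhl21 (-3.08) and Cdkn1a (-2.94), and without a size for Cx3cr1 (adjusted p = 0.000757), Adgrg5 (adjusted p = 0.0121) and LOC100048556 (adjusted p = 0.0211). The pooled test behind these values made many false calls on simulated data, 60.3% against the mean and 70.9% against liver.

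Few genes were called in the tumour (0, limma) and in the liver (51), the tissues with dim arrays among the fasted mice. Leaving out tumour fasted replicate 3, the dimmest array, gave 0 calls in the tumour, under the bound of 100 set beforehand against that array as the cause. That bound was wrong, since simulated data without the array recovered only 16 of 100 changes of 4-fold and 0 of 100 of 2-fold. With array weights, which gave that array 0.061, genes were called in the tumour, as they were with all arrays in 1 fit. Those counts are given further below. Tumour fasted replicate 3 thus stays open as a cause. With that array left out, the SD of log2 fold changes beyond their error was taken over 1209 genes bright in tumour and muscle. It was 0.234 in tumour (95% bootstrap interval 0.193 to 0.274) and 0.789 in muscle (0.740 to 0.836). The bootstrap drew genes, which are not independent replicates, so its intervals do not cover the spread between mice. Over 1291 genes bright in tumour and heart that SD was 0.245 in tumour and 0.461 in heart, a smaller gap. A smaller response of the tumour is thus another candidate explanation. In liver the most calls with either dim array left out were 22, under the same bound, but leaving out either keeps the other beside the bright replicate 2, without which there were 1799, so dim arrays and a weak response cannot be told apart in liver.

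Slow fibre markers stood higher in fasted muscle by 2.75 (log2). Their mean ranged over 3.09 among the 3 fed arrays alone, more than that difference, which is consistent with pieces of muscle that held different shares of slow fibres. The lowest fasted array lay 1.40 above the highest fed array, less than the range among the fed ones, so a rise with fasting stays open and cannot be told apart from sampling with 3 arrays per diet.

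Macrophage, endothelial and fibroblast markers stood lower in fasted tumours. The 3 medians lay at percentile 0 among 10000 random lists matched on the level in fed tumours. This was the outcome set beforehand against weak transcripts lost on dim arrays. It shows that level alone did not give such medians among genes drawn independently, but it cannot exclude that loss. The lists had already passed camera on the same fold changes, and the draws left out the correlation among markers. Loss that differs between probes of equal level was not matched either. Without tumour fasted replicate 3 the highest camera adjusted p was 0.00102, which argues against that array alone. All 9 list medians of the fasted arrays lay below the fed mean, with -0.75, -0.60 and -0.82 on the bright replicate 2, which restates the pattern and decides nothing. Weak transcripts lost on dim arrays, fewer such cells per tumour cell in fasted mice and the part of the tumour sampled all stay open. Without fasted replicate 1 the camera adjusted p was 0.0968, 0.0908 and 0.238, and with an estimated correlation the adjusted p was 0.535 for each, and by fry 0.261 for each.

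With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1693 calls in heart against at most 4 in any other, 51 against 0 in liver, 3475 against 0 in muscle, and 0 against 0 in the tumour, where all 10 splits thus tied; in the first 3 tissues only 1 of the 10, the real one, reached its count. For the differences from the tumour, splits of the 6 mice gave 217 against 20 (mean), 40 against 5 (heart), 387 against 13 (liver) and 555 against 8 (muscle), again in 1 of 10.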

How the results depend on the processing

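Tests chosen after the data were seen are the fits without the 3 arrays under 20% detected and with 1 weight per tissue. Of the counts, that in muscle moved by over 1.5 times only with all arrays in 1 fit. That in the tumour stayed at 0 except with array weights and in that 1 fit. No named gene changed direction while past the threshold in both. Direction was not compared for the other called genes. With median scaling the medians of ribosome biogenesis in liver (-0.41) and of acute phase proteins (-0.31) and neutrophil markers (-0.38) in the tumour changed sign, while camera, which sets a list against the other genes, kept its direction and its call. Leaving out 1 array gave 412 to 2393 calls in heart, 0 to 1799 in liver, 2509 to 2956 in muscle and 0 in the tumour, 54 to 1326 for the tumour against the mean, 12 to 548 against heart, 178 to 1354 against liver and 224 to 1417 against muscle, 317 to 1452 genes shared between tissues and 27 to 38 lists.

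Other counts are set against 1693 (heart), 51 (liver), 3475 (muscle), 0 (tumour), 217, 40, 387 and 555 (tumour against mean, heart, liver and muscle), 1044 shared genes and 34 lists; the cause of the moves was not tested unless given. Median scaling gave 0 in heart and 0 in liver, 1 against the mean, 9 against heart, 10 against liver, 184 against muscle and 0 shared. The z-score of log signal and the deposited score table, which are the same values, both gave 186 in heart, 22 in liver and 140 shared. No background correction gave 177 in liver, 338 against the mean and 80 against heart. Normalization within each tissue gave 175 in liver, 384 against the mean, 141 against heart and 885 against muscle. No filter gave 28 in liver and 80 against heart, and requiring detection on all 6 arrays, which tests fewer genes, gave 135 against the mean, 21 against heart, 204 against liver, 353 against muscle and 22 lists. A trended robust variance gave 116 in liver. Array weights gave 3888 in heart, 475 in liver, 1288 in the tumour, 2669 against the mean, 2273 against heart, 665 against liver, 3393 against muscle and 2328 shared; the weights ran from 0.061 (tumour fasted replicate 3) to 24.9 (liver fed replicate 2), estimated from 6 arrays. An adjusted p below 0.1 gave 228 in liver, 570 against the mean, 90 against heart, 682 against liver, 882 against muscle and 1629 shared. All 24 arrays in 1 fit, which shares 1 spread, gave 271 in heart, 1542 in liver, 1328 in muscle, 316 in the tumour and 458 shared. Without the 3 dim arrays, which leaves 1 fasted liver array that is assumed to vary like the fed ones, counts were 318 in liver, 1121 against the mean, 355 against heart, 800 against liver and 1661 against muscle, and 1 weight per tissue gave 4, 18, 51 and 336 for the 4 comparisons with the tumour. Mouse as a random block gave 319, 54, 499 and 674 for these, with every gene called without the block among them. With the correlation estimated, 0 lists passed.

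The second title letter shared between diets is only a letter: deviations of same-letter arrays correlated from -0.236 to 0.435, not all above 0.1. The replicate block on that letter gave 98 calls in liver and ended 5 named heart calls. The chip block was not run because no chip number was read. Named gene calls were lost most often with median scaling (75), on the z-score scale (32), with the series matrix values (32), without a filter (29) and with all arrays in 1 fit (26), and list calls with an estimated correlation (34), without a filter (9), with median scaling (7) and with detection on all 6 arrays (7). Low signal over background limits liver and tumour most, where 10.3% and 9.13% of probes were detected on the dimmest arrays.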

Other observations

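The comparison of neutrophil markers between tissues was chosen after the data were seen, and the clock genes were named after their values were seen. Of 13 clock genes tested in each of heart and muscle, 7 rose and 2 fell in heart and 7 rose and 3 fell in muscle. The counts were 7 and 2 in heart and 8 and 3 in muscle adjusted over the list alone. In fasted heart Nr1d1, which encodes the repressor REV-ERB alpha, rose by 2.05 ± 0.17 and the cryptochrome gene Cry2 by 1.31 ± 0.15, while the output gene Dbp fell by 1.72 ± 0.16 (log2, SE, n = 3). In fasted muscle Cry2 rose by 3.21 ± 0.20 and Nr1d1 by 1.68 ± 0.25, and Dbp fell by 2.999 ± 0.18. Arntl, which encodes the clock activator BMAL1, rose by 3.52 ± 0.27 in muscle, where 1 of 3 fed arrays detected it, and was at least 2.94-fold higher in heart, where no fed array did. Per3 was at least 2.55-fold lower in muscle, where no fasted array detected it. These calls held with each single array left out that allowed a test (adjusted p up to 0.0263 in heart and 0.00254 in muscle). Those in heart were lost with median scaling (adjusted p = 0.956), and those of Nr1d1 (0.0682) and Cry2 (0.142) in heart on the z-score scale. As a list the clock genes did not pass camera in heart (adjusted p = 0.0533, and adjusted p = 0.478 with an estimated correlation) or muscle (0.138, and adjusted p = 0.724 with an estimated correlation), and by fry the adjusted p was 0.0303 in heart and 0.0566 in muscle.

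The skeletal muscle actin gene Acta1, named after its values were seen, read 8.29 in tumour fed replicate 1, against 4.34 and 4.40 in the other fed tumours and 4.26 to 4.28 in the fasted ones. The level of neutrophil markers was compared between tissues over the 6 mice, 6 pairs in all, with exact permutation of the pairings. Liver and muscle had r = 0.968 (exact p = 0.00833, adjusted 0.05) and rho = 0.829 (exact p = 0.0583), but r = 0.509 without the 2 mice farthest from the median, so the relation rests on those mice; within a diet only 3 mice remain. Heart and tumour had r = 0.888 (exact p = 0.0764, adjusted 0.222) and rho = 0.657 (exact p = 0.175), and r = 0.924 without the 2 farthest mice. The 4 other pairs of tissues had r from 0.156 to 0.661, with adjusted p from 0.222 to 0.815. Of 56 means of cell type markers, by list and tissue, 13 had fasted and fed arrays that did not overlap. These were 3 in heart, 2 in liver, 4 in muscle and 4 in the tumour. Chance gives 10%, but genes at large did not overlap in 45.0%, 28.2%, 56.9% and 19.7% of cases in these tissues. The 13 therefore do not set markers apart from other genes. Among them were 8 slow fibre markers in liver (4.42 to 5.30 against 5.66 to 5.99), 8 cardiomyocyte markers in the tumour (4.69 to 5.96 against 4.57 to 4.64) and 3 epidermis markers in muscle (5.21 to 5.38 against 5.58 to 5.62, log2). These means lay near background, but not every member did. Tnnc1, named after its values were seen, read 8.95, 8.12 and 7.61 in fed liver replicates 1, 2 and 3, each of which detected it. No fasted liver array detected it, at 4.56 to 5.26. Only 3 slow fibre markers in liver and 1 epidermis marker in muscle were tested, and no tumour array detected Myl7 or Myh6. Tumour Nppa read 7.07, 5.07 and 10.77 in fasted replicates 1, 2 and 3, highest on the dim one. With median scaling the 3 differences were -0.64, 0.12 and -0.18, against -0.87, 0.56 and -0.30 here.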
